A study of Homo sapiens with 74 samples.

How the data were processed

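The series measured gene expression by RNA sequencing in human macrophages. Per the labels, CD14+ cells from blood mononuclear cells were kept for 1 day in M-CSF, a macrophage growth factor, at 10 ng/mL. They were then cultured alone or in transwells with synovial fibroblast lines, which share the medium but not the surface with the macrophages. The inflammatory cytokine TNF was given at 20 ng/mL, with or without a drug. The fibroblast lines were grown from joint tissue removed at knee replacement and used from passage 4 on.

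The deposited tables hold counts, that is whole numbers of reads per gene symbol with no normalisation, in 1 column per library. Per the submitters' processing notes, reads were aligned with STAR 2.4.2a to the hg19 build and counted with HTSeq 0.6.0. Libraries were made from polyA RNA, with single-end reads in the 1-day set and paired-end reads in the 2-day set. The annotation and the strand setting were not given in the sources used here. A spreadsheet had turned 28 gene symbols into dates, and these were left out of every named list. The labels list 74 samples, 70 from the 1-day set and 4 from the 2-day set. Columns were matched to samples by name, which gave 60 of 70 columns in the 1-day table and 4 of 8 in the 2-day table. The 10 labelled samples without a matching column were not analysed here. They were number 1 of MTF_Tofa and MT_Sulf, number 2 of MTF_Naprox and MT_Meth, and number 4 of AG, A77 and Naprox in both cultures. The 10 and 4 columns that match no sample were not used.

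Totals ranged from 20238956 to 45735565 counts per library in the 1-day set and from 27261453 to 32879556 in the 2-day set. A count of 0 therefore allows up to 3 counts, or 0.0656 to 0.1482 CPM, the count scaled to a standard library total (counts per mega-count). Reads carried no molecular identifiers, so this limit covers counting error only.

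Groups came from the sample titles: M (no TNF), MT (TNF), MTF (TNF with fibroblasts), and MT or MTF with a drug. The titles also number the samples 1 to 4. The titles of the 2-day set give all 4 libraries the same donor number. The labels of the 1-day set do not say whether its numbers are donors or separate cultures, so the p-values below measure only the spread between these samples. Each library was expressed as its deviation from its group's mean, and these deviations were correlated across the 5000 most variable genes. Of the libraries with a partner, 57 of 57 correlated best with a library of their own number in another group. The number was therefore used as a block in an alternative fit. The main fit, set out in advance, gives the lead counts below and leaves the numbers out. A lack of calls in the main fit therefore does not show that a drug had no effect. Within-number correlation of the deviations among M, MT and MTF ranged from 0.081 to 0.74, against -0.376 to 0.054 between different numbers. Subtracting the group mean by itself pushes the values between different numbers down, so part of this gap is built in.

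Each comparison was tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F-tests on the counts with TMM scaling, filterByExpr and 1 mean per group. P-values were adjusted by Benjamini-Hochberg, and the threshold was 0.05. The fit over all 60 libraries tested 15474 of 23710 genes. Each drug was compared with the control libraries of the same numbers, and the other libraries of those numbers shared the estimate of spread. Errors of log2 fold changes are standard errors (SE) and errors of CPM are standard deviations (SD). Named genes had a mean log2 CPM of at least 2, after a prior count of 2, and the same direction in every number compared. The rule took the 10 largest changes in each direction for TNF and fibroblasts, 5 for drugs in coculture, and 3 for drugs in monoculture and for culture differences. Where fewer than 5 passed in coculture, calls from the fit with the number as a block filled the places. XIST, Y-linked genes and genes that common variants switch off were never named, and a few further genes that the rule chose are not reported here. Gene positions are from GENCODE 44 mapped to GRCh37, which gave a position for 20574 gene rows by symbol, and older symbols are printed as in the table.

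Gene lists were tested with camera in limma 3.58.1 on 21 pathway lists and on lists of cell type markers, with an inter-gene correlation preset at 0.01. Tests were repeated with an estimated correlation. Of 630 pathway tests, 188 passed at an adjusted p of 0.05, 15 of them also with an estimated correlation. List members were counted over all genes tested and adjusted over the list alone. To ask how drugs acted on genes that fibroblasts had changed, such genes were picked in numbers that the drug test did not use. They had a log2 fold change of at least 1 in the same direction in both numbers. For most drugs they came from numbers 3 and 4 and were tested in 1 and 2. For Naprox they came from 2 and 4 and were tested in 1 and 3, and for AG from 1 and 4 and tested in 2 and 3. The 2-day set has 1 library per group and was described by log2 ratios with 1 CPM added, for genes of at least 10 CPM in 1 of the libraries. Its list medians were set beside 10000 random lists matched on expression in 20 bins.

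The comparisons, lists, naming rule and a first set of other settings were chosen before the data were examined. The numbers available per drug differed from that plan, because 10 samples had no column. Tofa in coculture and Meth and Sulf in monoculture had 1 library and were not tested in the planned way. A test with pooled spread and the number as a block, added later, gave 0 genes for each of these 3.

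The other settings set out in advance were the block, DESeq2 1.42.0, size factors by ratio to the median, no filter on low counts, a fit of the compared groups alone, and leaving out each number. For drugs with 2 numbers, leaving out a number left a lone library in an arm, which was assumed to vary like the other groups. After the data were seen, a scan looked for transcripts shared between libraries, and fits without the libraries in doubt were added. The scan took genes of at least 20 CPM in 1 library that lay at or below 0.05 of that level in every other library of a second library's group. For each of 2245 pairs with at least 8 such genes, the share of that level found in the second library was computed, and the spread of the shares was compared among pairs with a median share of at least 0.05. Negative binomial counts with known changes of 2-fold were simulated, with no difference between numbers. There the design of the TNF comparison recovered 43.3% of genes and that of Dex in coculture 17.9%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the remaining tables and the plots.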

Results

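Gene expression was measured by RNA sequencing in macrophages grown from human blood CD14+ cells. The 1-day set held 60 libraries. Macrophages alone (M), with TNF (MT) and with TNF and synovial fibroblasts (MTF) had 4 libraries each, numbered 1 to 4. The rest carried a drug on top of TNF, alone (monoculture) or with fibroblasts (coculture). In coculture Triple, A77 and Aur had 3 libraries each. Dex, Diclo, Hydrox, Meth, Sulf, Naprox and AG had 2, and Tofa had 1. In monoculture Triple, A77, Aur and Naprox had 3, Dex, Diclo, Hydrox, Tofa and AG had 2, and Meth and Sulf had 1. Aur is auranofin, Dex dexamethasone, Tofa tofacitinib, Hydrox hydroxychloroquine, Meth methotrexate, Diclo diclofenac, Sulf sulfasalazine, AG an inhibitor of the EGF receptor kinase and Naprox naproxen. The labels do not spell out A77 and Triple and give no doses. Total counts ran from 20238956 to 45735565 per library. The 2-day set held 4 libraries of 27261453 to 32879556 counts, 1 per group. Levels are CPM ± SD over the numbers compared, and changes are log2 fold changes ± SE, with adjusted p-values from edgeR. Genes chosen by the naming rule moved in the same direction in every number compared.

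Before the comparisons, 7 libraries need a remark, because they held transcripts of another library of the same number at a nearly constant share. In macrophages without TNF, F13A1, a clotting factor subunit of unstimulated macrophages, stood at 1570 CPM in M library 2. In MTF_Triple library 2 it stood at 634 CPM, whereas it stayed under 15 CPM in the other MTF_Triple libraries. ZBTB16, a glucocorticoid-induced transcription factor, reached 38.2 CPM in MTF_AG library 2, which had no dexamethasone, and 0.158 CPM in MTF_AG library 3. It reached 36.4 CPM in MT_AG library 2 and 18.9 CPM in MT_Tofa library 1. Over 65 genes of MTF_Triple library 2, M library 2 held a median share of 0.63, and the upper quartile of the shares was 1.08 times the lower. MT_AG and MT_Dex library 2 shared in both directions, as did MTF_AG and MTF_Dex library 2 and M and MTF_Triple library 2. MT_Tofa library 1 held a share of 0.192 of 62 genes of MTF_Dex library 1. Of 2245 pairs scanned, 703 had a median share of at least 0.05, and 7 of these had a quartile ratio under 1.3, all between libraries of the same number, and the next ratio was 1.34. An eighth library, MT_Triple library 2, carried endothelial transcripts and is described with Triple. Counts without these 8 libraries were added after the data were seen and are given with each comparison that had calls. That fit holds 1 library of AG and of Dex in each culture and 1 of Tofa in monoculture, assumed to vary like the other groups.

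**Figure D1:**
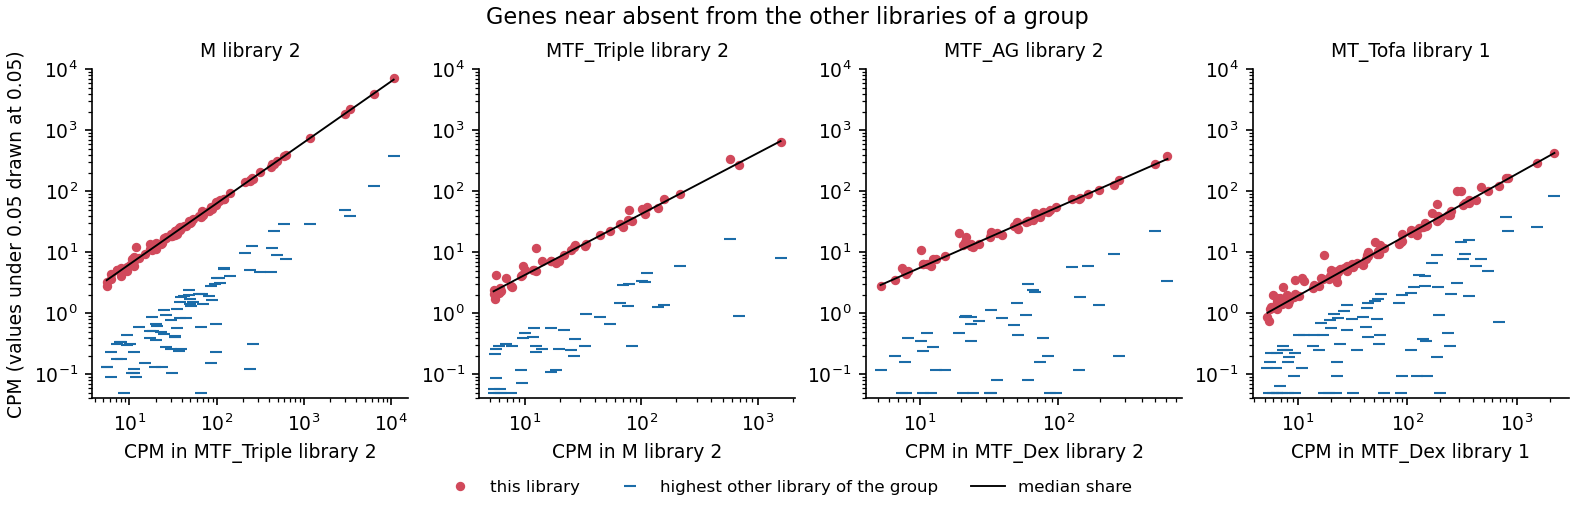
Each panel plots, on log axes in CPM, genes that are high in a giving library and low in the rest of the receiving library's group; dots are the receiving library, ticks the highest other library of its group and the line the median share. In M library 2 against MTF_Triple library 2 the dots follow the line at a share of 0.63, and the share is 0.554 for MTF_AG library 2 against MTF_Dex library 2.

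The first comparison asked what TNF does to macrophages cultured alone (MT against M, 4 libraries each). TNF raised NF-kB targets and lowered genes of resident-type macrophages, but the second list did not pass with an estimated correlation between genes (0.397). It altered 5163 of 15474 genes, with 2594 raised and 2569 lowered. The fit lacking number 3 gave 2925. Without the 8 libraries in doubt, among them M library 2, the count was 5501. All 20 named genes kept their calls in that fit, and most raised ones had larger changes, such as LAD1 at 9.43 (from 7.20), IDO1 at 8.48, TNFAIP6 at 8.11, MAP1LC3A at 7.81 (from 6.41) and ACHE at 9.93.

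Among the genes that TNF raised most, ACHE, the enzyme that breaks down acetylcholine (chromosome 7, 100487615 to 100494594 in GRCh37), rose by 8.54 ± 1.41 (adjusted p = 1.04e-05). Its level was 0.426 ± 0.54 CPM in M and 158 ± 83.5 in MT (n = 4). IL2RA, a receptor chain for interleukin 2, rose by 7.80 (adjusted p = 9.09e-05). TNFAIP6, a secreted matrix-binding protein (chromosome 2, 152214106 to 152236560), rose by 6.77 ± 0.90 (adjusted p = 3.33e-07). IDO1, which breaks down tryptophan (chromosome 8, 39759794 to 39786309), rose by 6.82 (adjusted p = 8.41e-05). The other raised genes were LAMP3, a lysosomal protein of mature dendritic cells, the filament protein LAD1, the membrane protein ADAM11, the transcription factor ARNT2, the chemokine receptor CXCR5 and the autophagy gene MAP1LC3A, with changes from 6.41 to 7.24.

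Among the lowered genes, F13A1 (chromosome 6, 6144317 to 6321246) fell by 9.33 ± 1.41 on the log2 scale (adjusted p = 2.69e-06), from 1740 ± 397 to 2.71 ± 1.61 CPM. FOLR2, a folate receptor of resident macrophages (chromosome 11, 71927645 to 71932994), fell by 8.51 ± 0.98 (adjusted p = 2.67e-08), from 309 ± 144 to 0.842 ± 0.205 CPM. The selenium carrier SEPP1 changed by -9.0 and the growth factor IGF1 by -7.60. The membrane protein MS4A6A, the mannose receptor MRC1, the iron exporter SLC40A1, the retinol enzyme DHRS9, the ribonuclease RNASE1 and the growth factor HGF changed by -9.21 to -6.76.

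By list, 21 of 26 NF-kB targets rose (24 adjusted over the list alone), with a median of 2.79 (adjusted p = 4.46e-18, and 0.0408 with an estimated correlation). They included the cytokine subunit EBI3 at 6.37, the chemokine CXCL1 at 4.49 and the inhibitors TNFAIP3 at 3.51 and NFKBIA at 3.04. IL1B rose by 2.41 in 3 of 4 numbers (adjusted p = 0.029), and by 6.20 without the libraries in doubt. TNF itself (adjusted p = 0.0749) and IL6 (-2.68, and 1.12 without those libraries) did not pass. Of 29 interferon-stimulated genes 9 rose (9 adjusted over the list alone), with a median of 1.18 (adjusted p = 0.0033, and 0.72 with an estimated correlation). CXCL11, CXCL10 and CXCL9, chemokines that draw T cells, changed by 5.37, 4.35 and 3.63. Of 20 genes of resident-type macrophages, 13 fell (14 adjusted over the list alone), with a median of -3.17 (adjusted p = 1.45e-06, and 0.397 with an estimated correlation). LYVE1, a hyaluronan receptor, changed by -7.92, while CD163 (-0.33) and C1QA (-0.38) did not pass. Among hypoxia and glycolysis genes 11 rose (12 adjusted over the list alone), among them EGLN3 at 4.07 and VEGFA at 1.63 (adjusted p of the list 0.00125, and 0.492 with an estimated correlation). Cholesterol synthesis genes had 5 raised and a median of 0.64 (adjusted p = 0.00125, and 0.72 with an estimated correlation), but 14 raised and a median of 1.67 without the libraries in doubt. Of 11 fibroblast markers 5 rose although no fibroblasts were in these cultures, COL1A1 from 0.0493 to 2.18 ± 1.33 CPM and LUM from 0.0285 to 1.93 CPM (adjusted p of the list 0.097).

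The next comparison asked what synovial fibroblasts add when TNF is present (MTF against MT, 4 libraries each). The fibroblasts raised genes of the epidermal growth factor (EGF) family. By list tests they also raised genes that respond to cyclic AMP (cAMP) and lowered interferon-stimulated genes, but neither list passed with an estimated correlation (0.0948 and 0.845). It altered 1729 genes, 787 raised and 942 lowered. With the number as a block the count was 3250. Leaving out number 3 gave 227, and 12 of the 20 named genes then lost their calls, namely CXCR7, PPBP, KCNE1L, CD93, CCL8, CXCL9, CXCL11, CHI3L1, FFAR2, ITGA11, ANTXR1 and C1QB. Leaving out number 1 gave 1096 and ended the calls of CD93, CHI3L1 and ANTXR1. Number 4 gave 992 and ended those of CD93, CXCL9, CXCL11 and C1QB, and number 2 ended that of CXCL11. None of the libraries in doubt is in MT or MTF, and without them the count was 1753 and CXCL11 lost its call (-3.98, adjusted p = 0.0631).

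Among the raised genes, HBEGF, an EGF receptor ligand (chromosome 5, 139712428 to 139726188), rose by 4.29 ± 0.76 (adjusted p = 0.000313). Its level was 24.5 ± 14.1 CPM in M, 9.62 ± 7.35 in MT and 189 ± 71.4 in MTF. SLC16A10, an amino acid transporter (chromosome 6, 111408706 to 111552397), rose by 5.28 ± 0.53 (adjusted p = 1.65e-08), from 3.08 ± 1.05 to 120 ± 25.9 CPM. EMR3, an adhesion receptor of myeloid cells, rose by 7.47 ± 1.09 (adjusted p = 2.48e-05). The chemokine-scavenging receptor CXCR7 rose by 5.69, the platelet chemokine PPBP by 5.05 and the cytokine OSM by 4.83. The transcriptional regulator MAMLD1, the potassium channel subunit KCNE1L, the surface protein CD93 and the chondroitin sulfate enzyme CSGALNACT1 rose by 4.41 to 4.88.

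Among the lowered genes, ANKRD1, a stress-induced muscle ankyrin protein (chromosome 10, 92671853 to 92680844), fell by 4.99 ± 0.92 (adjusted p = 0.000472), from 33.7 ± 15 to 1.04 ± 0.32 CPM. TLR7, a receptor for single-stranded RNA (chromosome X, 12885191 to 12908480), fell by 2.86 ± 0.52 (adjusted p = 0.000394). The chemokines CCL8, CXCL9 and CXCL11 changed by -4.31, -3.96 and -3.94. The chitinase-like protein CHI3L1, the fatty acid receptor FFAR2, the integrin ITGA11, the collagen receptor ANTXR1 and the complement gene C1QB made up the rest.

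Of 17 cAMP-responsive genes, 9 rose (10 adjusted over the list alone), with a median of 1.45 (adjusted p = 6.12e-08, and 0.0948 with an estimated correlation). CREM, a cAMP-induced repressor (chromosome 10, 35415719 to 35501886), rose by 2.11 (adjusted p = 8.82e-11), from 15.6 ± 1.97 to 67.2 ± 10.0 CPM. The nuclear receptor NR4A1 rose by 4.09 and the matrix protein THBS1 by 3.09. Of 8 genes of the EGF family and its receptors 5 rose, with a median of 3.82 (adjusted p = 0.000806, and 0.0181 with an estimated correlation): NRG1 by 4.31, HBEGF by 4.29, TGFA by 4.11, EREG by 3.90 and EPGN by 3.73. Of 29 interferon-stimulated genes 3 fell, among them CXCL9 and CXCL11 (1 adjusted over the list alone). The list median was -1.35 (adjusted p = 2.5e-06, and 0.845 with an estimated correlation). CXCL10 went from 231 ± 205 to 29.2 ± 38.9 CPM, a change of -2.98 (adjusted p = 0.103). PTGS2, which starts prostaglandin synthesis, rose by 2.69 (adjusted p = 0.0159). Of the NF-kB targets only IL1A, at 3.48, rose (adjusted p of the list 0.938), and IL6 changed by 4.30 (adjusted p = 0.0719). Cholesterol synthesis genes had a median of -0.65 and no calls over all genes (adjusted p = 0.000806, and 0.845 with an estimated correlation). Adjusted over the list alone, 3 of them fell. The fibroblast markers had only PDGFRB raised, by 1.59 (adjusted p = 0.0334).

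**Figure D2:**
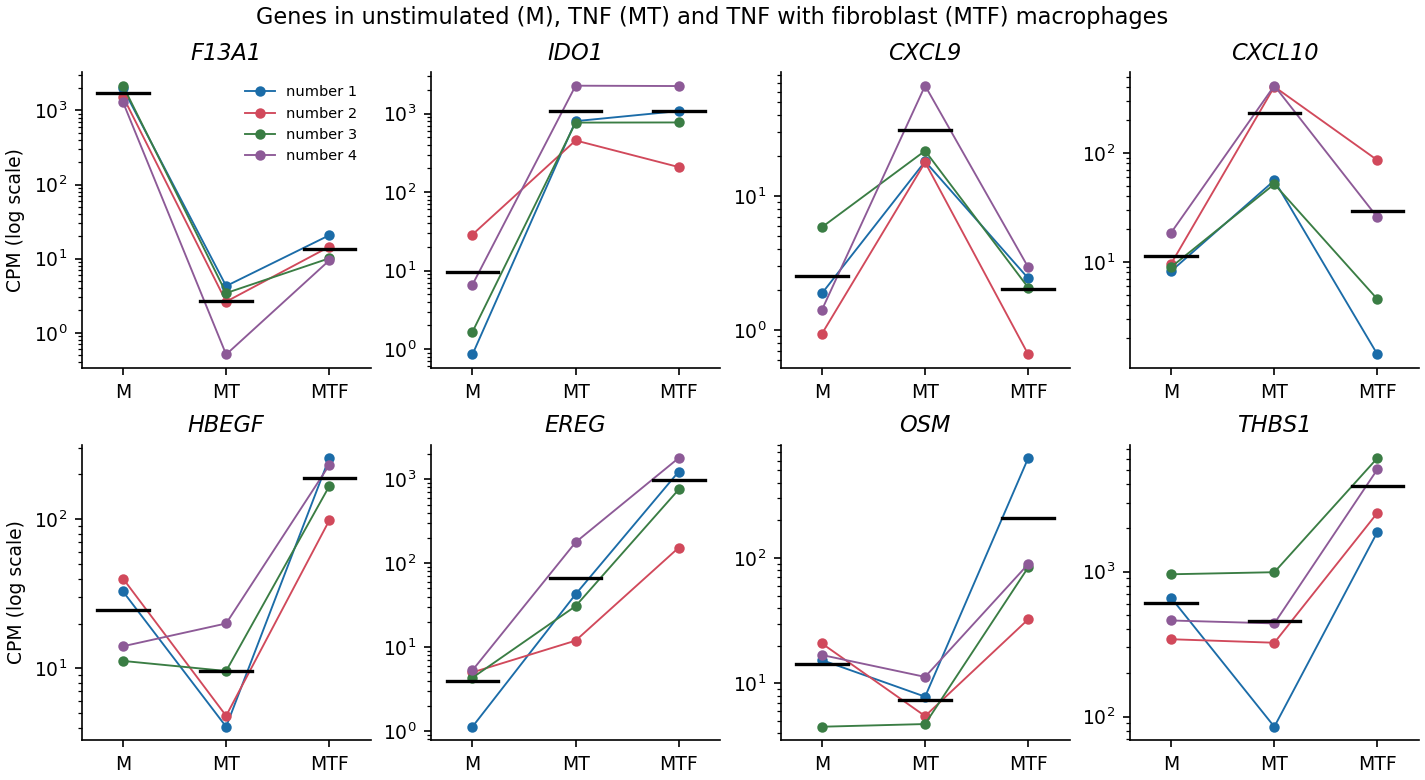
CPM on a log scale of F13A1, IDO1, CXCL9, CXCL10, HBEGF, EREG, OSM and THBS1 in each of 4 libraries of M, MT and MTF; lines join libraries of the same number and bars are means. F13A1 drops from a mean of 1740 CPM in M to 2.71 in MT, and HBEGF climbs from 9.62 in MT to 189 in MTF.

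Compared with macrophages without TNF, coculture with TNF (MTF against M, 4 libraries each) asked for the joint effect. By list tests resident-type genes were lowered and NF-kB and cAMP genes raised, but none of these lists passed with an estimated correlation (0.275, 0.0545 and 0.275). It altered 5551 genes, with 2775 raised and 2776 lowered. A fit without number 3 gave 3208 and one without the libraries in doubt 5740. EREG, an EGF receptor ligand (chromosome 4, 75230862 to 75254466), rose by 7.96 ± 1.33 (adjusted p = 1.24e-05), from 3.95 ± 1.92 CPM in M to 985 ± 698 in MTF. The secreted protein C1QTNF1 rose by 7.66 ± 1.04 and the cytoskeletal gene SHROOM3 by 7.20; without the libraries in doubt these were 10.71 and 10.58. SEPP1 changed by -10.60, DHRS9 by -8.87, IGF1 by -8.35 and F13A1 by -6.99. The remaining named genes raised were IL2RA, CXCR7, CXCR5, LAD1, LAMP3, IDO1 and MET, and those lowered FOLR2, HGF, CD180, SLC40A1, MS4A6A and GGTA1P. Of the NF-kB targets 23 rose, also adjusted over the list alone (adjusted p = 4.53e-17, and 0.0545 with an estimated correlation). Of the cAMP genes 11 rose, and 12 adjusted over the list alone (adjusted p = 1.78e-05, and 0.275 with an estimated correlation). Of resident-type genes 15 fell, also adjusted over the list alone (adjusted p = 1.37e-06, and 0.275 with an estimated correlation).

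The drug comparisons asked which genes a drug changes in TNF-treated macrophages, with and without fibroblasts. A77 in coculture lowered genes that fibroblasts had raised. It changed 132 genes (49 raised, 83 lowered; numbers 1 to 3), and 1069 with the number as a block. A fit without number 3 gave 2 genes, and all 10 named genes lost their calls. Without number 1 it gave 199 and HEY1 and EMR3 lost theirs, and without number 2 it gave 236 and C1QB, SCFD2, BZW2, SFXN4 and CXCR7 lost theirs. PID1, an insulin-signaling adaptor (chromosome 2, 229715242 to 230136003), fell by 3.95 ± 0.62 (adjusted p = 0.000786), from 483 ± 148 CPM in MTF to 31.3 ± 24.5. KCNE1L changed by -6.09, CXCR7 by -6.00, the Notch target HEY1 by -5.24 and EMR3 by -5.02. C1QB rose by 3.5 (adjusted p = 0.0401), SCFD2 by 1.89, BZW2 by 1.82, SFXN4 by 1.58 and FAM213A by 1.52. The count was 133 without the libraries in doubt, and C1QB (3.54), SCFD2 (1.92), BZW2 (1.86) and SFXN4 lost their calls (adjusted p from 0.0557 to 0.0788) with changes as large as before. Of the cAMP genes CREM (-1.73) and the G-protein regulator RGS2 (-2.95) fell, 10 adjusted over the list alone. The list's adjusted p was 3.24e-09, and 0.110 with an estimated correlation. In monoculture edgeR called 0 genes for A77, with 543 at an unadjusted p under 0.05, and DESeq2 called 14.

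Naprox in coculture also lowered genes that respond to cAMP as a list, which did not pass with an estimated correlation (0.0732). It changed 134 genes (62 raised, 72 lowered; numbers 1 and 3), and 754 with the number as a block. Leaving out either number gave 0 genes and ended all 10 named calls. SLC16A10 fell by 3.99 ± 0.55 (adjusted p = 0.00503), from 130 ± 30.5 to 8.3 ± 3.65 CPM. KCNE1L fell by 7.34 ± 0.98, and the peptide receptor CALCRL, EMR3 and the scaffold gene GRASP changed by -5.03 to -4.58. MYC, a growth-promoting transcription factor (chromosome 8, 128747680 to 128755197), rose by 4.21 ± 0.73, from 2.88 ± 1.68 to 53.6 ± 17.1 CPM (adjusted p = 0.0192). The membrane repair gene MYOF, the polyamine enzyme ODC1, the lipid phosphatase PPAP2B and the lysosomal lipase LIPA rose by 2.34 to 3.44. CREM (-1.83), NR4A2 (-3.71) and PDE4B (-2.56) fell among the cAMP genes, 10 adjusted over the list alone. The list's median was -2.18 (adjusted p = 5.28e-09, and 0.0732 with an estimated correlation). PTGS2 changed by -3.54 (adjusted p = 0.0458). None of the libraries in doubt holds Naprox, and without them the count was 135. In monoculture edgeR called 0 genes, with 401 at an unadjusted p under 0.05, and DESeq2 called 9. Lipid-sensing receptor targets (LXR and PPAR) had a median of 0.56 there (4 raised adjusted over the list alone; adjusted p = 4.75e-08, and 0.0045 with an estimated correlation).

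AG in coculture, which blocks the EGF receptor, lowered fibroblast-raised genes, but few genes passed on their own. It changed 8 genes (4 raised, 4 lowered; numbers 2 and 3), and 206 with the number as a block. MTF_AG library 2 carried Dex transcripts, and without the libraries in doubt edgeR called 0 genes, with 1995 at an unadjusted p under 0.05; DESeq2 called 425 with all libraries. Leaving out number 2 gave 0 genes and leaving out number 3 gave 27, with CREM the only named gene to pass. The named genes were APEX1 (1.39), MBLAC2 (1.15) and C3orf58 (1.03), and among those lowered ID3 (-3.34), PDE4A (-1.47), CREM (-1.40) and SLX4 (-0.71). All 7 lost their calls without the libraries in doubt, with adjusted p from 0.076 to 0.155, but that fit holds 1 AG library in coculture. Changes stayed similar there, with APEX1 at 1.24, PDE4A at -1.64 and CREM at -1.22. SMAD3, ALS2CL and PPBP passed only with the number as a block. HBEGF changed by -3.13 (adjusted p = 0.106). In monoculture edgeR called 0 genes, with 564 at an unadjusted p under 0.05, and DESeq2 called 22. Targets of the aryl hydrocarbon receptor had a median of -0.97 there (adjusted p = 1.34e-05, and 0.0164 with an estimated correlation). That p was 0.00173 without the libraries in doubt, where 1 AG library remained, and 0.098 with an estimated correlation.

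Dex is a glucocorticoid, and in both cultures it raised the known targets of its receptor. In coculture it changed 147 genes (109 raised, 38 lowered; numbers 1 and 2), and 430 with the number as a block. Leaving out number 1 gave 2 genes and ended the calls of FBLN5, ZBTB16, IL18R1, AMPH, ABLIM3, CD226, CST7, OLR1 and CALCRL. Number 2 gave 12 and ended these but for CD226. ZBTB16 (chromosome 11, 113929763 to 114127487) rose by 9.45 ± 1.49 (adjusted p = 0.00232), from 0.151 ± 0.12 to 97.9 ± 34.1 CPM. FBLN5, an elastic-fiber protein (chromosome 14, 92335755 to 92414331), rose by 10.45 ± 1.75 (adjusted p = 0.00304). The cytokine receptor IL18R1 and the genes AMPH and ABLIM3 rose by 7.47 to 8.25. CD226, an adhesion receptor, fell by 5.83 ± 0.93 (adjusted p = 0.00232), and the protease inhibitor CST7 and the scavenger receptor OLR1 changed by -4.69 and -4.45. CALCRL fell too (adjusted p = 0.0125). Dex library 2 of each culture shared transcripts with AG library 2. With the libraries in doubt left out, 1 Dex library remained and 128 genes passed, but CST7 (-5.70, adjusted p = 0.173) and OLR1 (-6.24, 0.0858) did not, although their changes were larger. Of 18 glucocorticoid targets 8 rose (13 adjusted over the list alone), with a median of 2.13 (adjusted p = 1.25e-20, and 0.000897 with an estimated correlation). FKBP5, a chaperone of the receptor, rose by 3.53, from 138 ± 46.4 to 1590 ± 217 CPM. Genes of the EGF family and its receptors had a median of -2.68 (2 lowered adjusted over the list alone; adjusted p = 0.00182, and 0.0205 with an estimated correlation, or 0.162 without the libraries in doubt). In monoculture 84 genes changed, 199 with the number as a block and 132 without the libraries in doubt. Leaving out number 1 gave 0 genes and number 2 gave 5, and each ended all 4 named calls. TFCP2L1, a transcription factor, rose by 8.61 ± 1.24 (adjusted p = 0.00106), the adenosine receptor ADORA3 and the decoy receptor IL1R2 also rose, and SRA1 changed by -0.80. SRA1 lost its call without the libraries in doubt (-0.90, adjusted p = 0.135), where 1 Dex library remained. The glucocorticoid list had 7 raised (12 adjusted over the list alone) and a median of 1.70 (adjusted p = 9.24e-22, and 0.000584 with an estimated correlation).

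Triple raised cholesterol synthesis and lysosomal genes in both cultures. In monoculture neither list passed with an estimated correlation (0.421 and 0.0834), but both did without the libraries in doubt (0.0338 each), where the lysosomal list in coculture did not (0.0538). In coculture it changed 1020 genes (561 raised, 459 lowered; numbers 1 to 3), and 2716 with the number as a block. A fit without number 3 gave 36 genes, and all 10 named genes lost their calls. Taking out number 1 ended those of CCL18, CCL8 and CHI3L1, and number 2 those of CD180 and CCL24. MTF_Triple library 2 carried M transcripts, and 617 genes passed without the libraries in doubt. TMEM97, a sterol-regulated membrane protein (chromosome 17, 26646226 to 26655711), rose by 4.27 ± 0.70 (adjusted p = 0.000278), and by 4.37 without them. EMR3 fell by 6.64 ± 1.22 (adjusted p = 0.00102), and by 7.81 without them. The chemokines CCL18 and CCL8 and the genes CHI3L1 and CD180 rose by 3.58 to 4.81, and PPBP, KCNE1L, CCL24 and CXCR7 changed by -6.35 to -5.78. Without the libraries in doubt CD180 (2.29 from 3.58, adjusted p = 0.284) and CCL24 (-6.16 from -6.12, 0.0615) lost their calls. Of 15 cholesterol synthesis genes 13 rose (15 adjusted over the list alone), with a median of 2.09 (adjusted p = 4.58e-24, and 0.0446 with an estimated correlation). HMGCS1, an early enzyme of the pathway, went from 53.6 ± 15.2 to 443 ± 110 CPM. Of 21 lysosomal genes 5 rose (6 adjusted over the list alone), with GPNMB at 2.65 and the cholesterol exporter NPC1 at 1.92 (adjusted p = 2e-06, and 0.0481 with an estimated correlation; 0.0538 without the libraries in doubt). The cAMP genes had 6 lowered (8 lowered and 1 raised adjusted over the list alone; adjusted p = 7.75e-06, and 0.184 with an estimated correlation), and 1 without the libraries in doubt. Of the resident-type genes CCL18 rose in 3 of 3 numbers and SEPP1, IGF1 and FOLR2 in 2 of 3 (7 adjusted over the list alone; adjusted p = 0.00551, and 0.83 with an estimated correlation). Of these only CCL18 rose without the libraries in doubt, and SEPP1 (-0.30), IGF1 (0.13) and FOLR2 (-0.27) did not pass.

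In monoculture Triple changed 1532 genes (1033 raised, 499 lowered), and 239 without MT_Triple library 2. With the number as a block the counts were 2697 and 953. A fit without number 3 gave 0 genes with edgeR, and without number 2 it gave 425. MT_Triple library 2 held endothelial transcripts, such as TIE1 at 218 CPM against at most 2.28 in any other library and CDH5 at 163 against 0.921. All 6 named genes lost their calls without it and without all 8 libraries in doubt, where 245 genes passed. Without the 8, COL4A2 went from 5.53 to 1.27 (adjusted p = 0.556) and TJP1 from 4.67 to 1.45 (0.262). The other 4 changed less, MS4A6A from 4.67 to 4.00 (0.0589), SHROOM3 from -3.87 to -3.58 (0.183), OLR1 from -3.64 to -3.38 (0.0644) and CXCL5 from -3.43 to -2.96 (0.161). The cholesterol synthesis list had 8 raised (11 adjusted over the list alone; adjusted p = 6.15e-10, and 0.421 with an estimated correlation), and 7 without the libraries in doubt. The lysosomal list had 7 raised (9 adjusted over the list alone; adjusted p = 8.81e-07, and 0.0834 with an estimated correlation), and 4 without them.

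**Figure D3:**
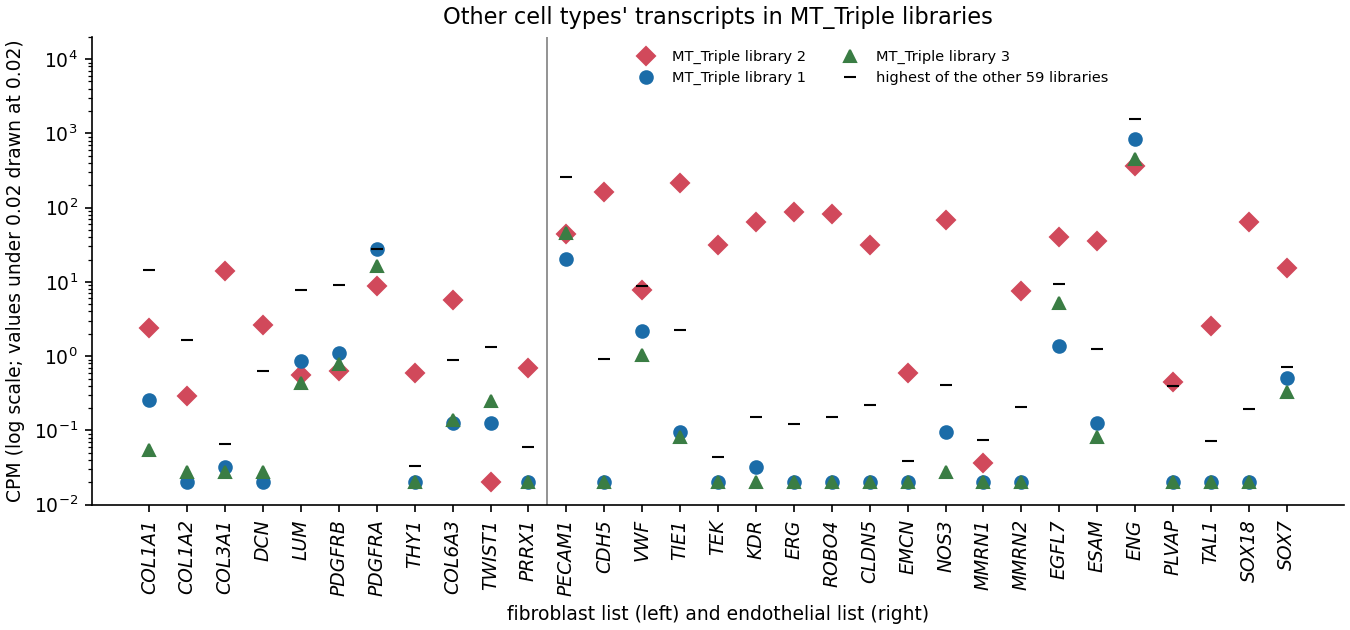
CPM on a log scale of endothelial and fibroblast marker genes in MT_Triple libraries 1, 2 and 3 and the highest value among the other 59 libraries. In library 2, 15 of 20 endothelial genes lie above every other library, with TIE1 at 218 CPM. So do 5 of 11 fibroblast genes, with COL3A1 at 14 CPM against at most 0.0654 elsewhere. COL1A1, at 2.4 CPM, lies below the highest other value of 14.6.

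Hydrox, an antimalarial that collects in lysosomes, raised the same lists as Triple, but the cholesterol list in monoculture did not pass with an estimated correlation (0.281). In coculture it changed 5 genes (numbers 1 and 2), and 39 with the number as a block. Leaving out either number gave 0 genes and ended all 5 named calls. INSIG1, a brake on sterol synthesis (chromosome 7, 155089486 to 155101945), rose by 2.55 ± 0.43 (adjusted p = 0.0217), from 193 ± 37.3 to 1130 ± 221 CPM. FAM213A, the receptor IL17RB, the sterol enzyme EBP and SCML1 rose by 1.48 to 2.67. CASP8 (-0.83) passed only with the number as a block (adjusted p = 0.0226). With the libraries in doubt left out, 11 genes passed, and FAM213A (adjusted p = 0.069) and EBP (1.95, 0.0676) did not, with changes as large as before. Of the cholesterol synthesis genes only INSIG1 rose over all genes, but 15 did so adjusted over the list alone (adjusted p = 6.22e-35, and 0.00807 with an estimated correlation). The lysosomal list had an adjusted p of 7.54e-12, and 0.00807 with an estimated correlation, with 5 genes raised adjusted over the list alone. In monoculture edgeR called 0 genes, with 1559 at an unadjusted p under 0.05, DESeq2 called 205 and the fit with the number as a block 53. It was 1 gene without the libraries in doubt. The lysosomal list had 11 genes raised there adjusted over the list alone (adjusted p = 2.12e-13, and 0.00577 with an estimated correlation). The cholesterol list had 8 (adjusted p = 4.94e-13, and 0.281 with an estimated correlation).

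Aur, a gold compound that blocks thioredoxin reductase, raised targets of the antioxidant factor NRF2 as a list, which did not pass with an estimated correlation (0.0598 in monoculture and 0.193 in coculture). In coculture it changed 76 genes (24 raised, 52 lowered; numbers 1 to 3), and 388 with the number as a block. A fit without number 3 gave 0 genes and ended all 10 named calls. Leaving out number 1 gave 21 and ended 7 calls, with HTRA3, BRCA2 and LDHB kept, and number 2 ended those of HTRA3, BRCA2, LRFN4 and RCN1. CYP27A1, a sterol hydroxylase (chromosome 2, 219646472 to 219680016), rose by 2.44 ± 0.39 (adjusted p = 0.00139), from 327 ± 262 to 1780 ± 182 CPM. LDHB, a lactate dehydrogenase subunit (chromosome 12, 21788276 to 21910791), fell by 1.52 ± 0.22 (adjusted p = 0.000417). HTRA3, TCN2, NMT2 and BRCA2 rose by 1.57 to 3.05, and MXI1, LRFN4, RCN1 and HMGN3 changed by -1.89 to -1.19. The count was 84 without the libraries in doubt, and HMGN3 lost its call (-1.2 from -1.19, adjusted p = 0.0683). In monoculture 674 genes changed (320 raised, 354 lowered), and 1540 with the number as a block. A fit without number 3 gave 19 and ended all 6 named calls, leaving out number 1 ended those of DPYSL3 and IL1R2 and number 2 that of NDRG2, and without the libraries in doubt the count was 758. TMEM173, the sensor adaptor also called STING, fell by 5.32 ± 0.74 (adjusted p = 5.26e-05), from 228 ± 122 to 5.7 ± 1.66 CPM. DPYSL3, IL1R2 and NDRG2 rose by 4.53 to 6.96, and MT1L and FPR1 changed by -6.19 and -5.07. Of 16 NRF2 targets, 6 rose in monoculture (14 adjusted over the list alone), with SRXN1, which repairs oxidized peroxiredoxins, raised by 1.90. Their adjusted p was 1.40e-14, and 0.0598 with an estimated correlation. In coculture the list had a median of 0.73 (3 raised adjusted over the list alone; adjusted p = 1.01e-10, and 0.193 with an estimated correlation).

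Diclo in coculture changed CREM by -1.6 ± 0.23 (adjusted p = 0.00682), its only call. Leaving out either number ended this call, and DESeq2 called 52 genes. Without the libraries in doubt CREM was again the only call. The cAMP list had a median of -2.19 (6 lowered adjusted over the list alone; adjusted p = 3.59e-14, and 0.0287 with an estimated correlation). The value with an estimated correlation was 0.249 without the libraries in doubt. The LXR and PPAR targets had an adjusted p of 4.14e-06, and 0.0177 with an estimated correlation, or 0.0684 without the libraries in doubt. In monoculture SORL1, a sorting receptor, rose by 3.46 ± 0.52 (adjusted p = 0.021), the only call. It was lost without either number and without the libraries in doubt (3.46 again, adjusted p = 0.154), where edgeR called 0 genes, with 946 at an unadjusted p under 0.05. With the number as a block 11 genes passed, and DESeq2 called 82.

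Meth and Sulf in coculture and Tofa in monoculture, with 2 libraries each, had few or no calls. Meth in coculture had 0 calls with edgeR, 252 genes at an unadjusted p under 0.05 and 6 calls with DESeq2. Sulf in coculture had 0, 638 and 5 by the same measures. Interferon-stimulated genes had a median of -1.42 under Meth (adjusted p = 2.16e-11, and 0.378 with an estimated correlation) and -1.18 under Sulf (1.07e-06, and 0.525 with an estimated correlation), with 0 genes passed in either list, also adjusted over the list alone. Tofa, which blocks JAK kinases, had 0 calls in monoculture with edgeR, 172 at an unadjusted p under 0.05 and 17 with DESeq2. MT_Tofa library 1 carried Dex transcripts. Targets of STAT3 and STAT5 had a median of -0.41 (adjusted p = 0.0058, and 0.355 with an estimated correlation), and -1.39 without the libraries in doubt, where 1 Tofa library remained (0.000431, and 0.389 with an estimated correlation).

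**Figure D4:**
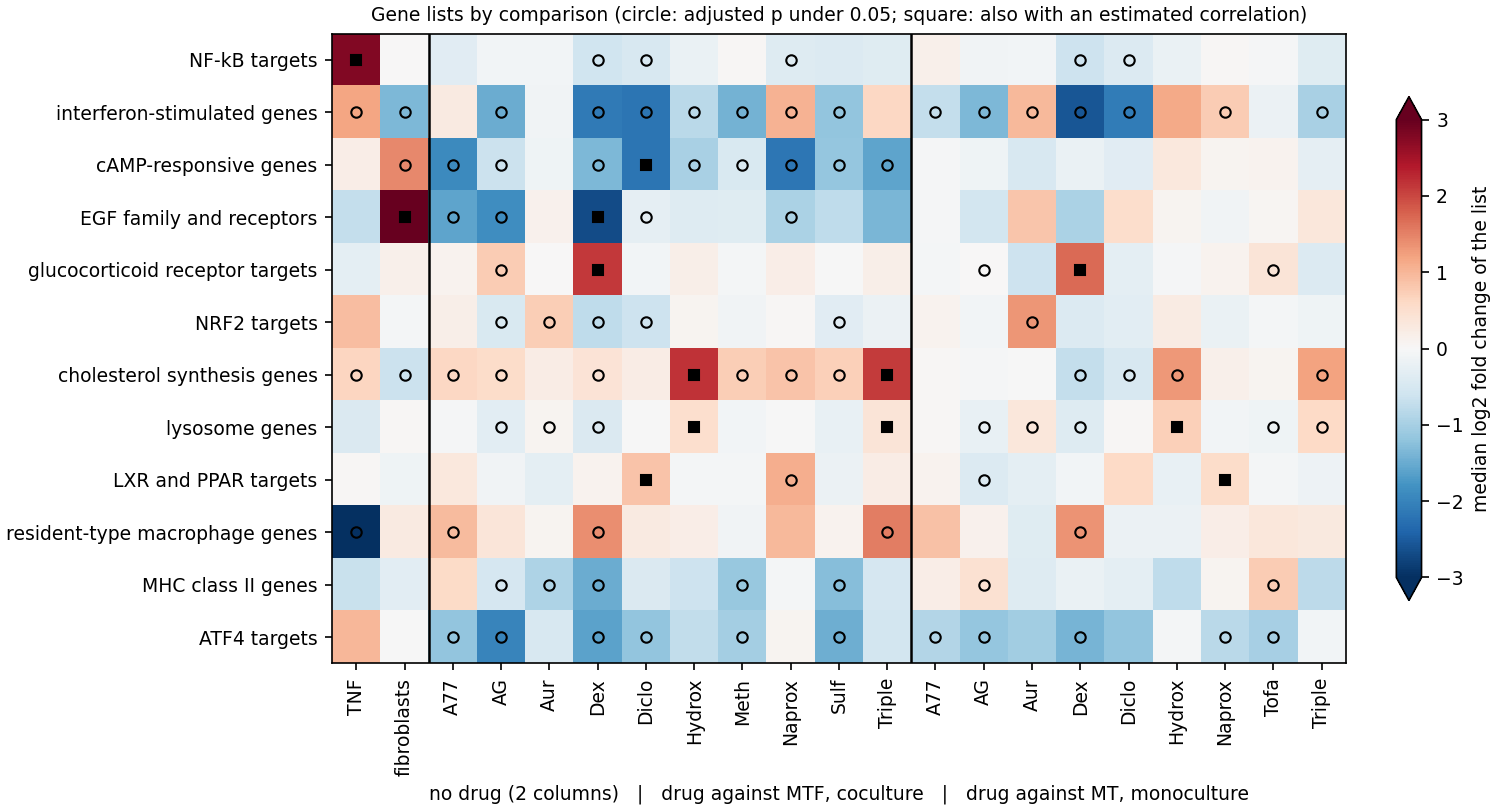
Median log2 fold change of 12 gene lists, in color, for each comparison; a circle marks an adjusted p under 0.05 with the preset correlation and a square one that also holds with an estimated correlation. The glucocorticoid list has a median of 2.13 under Dex in coculture, and the cAMP list one of -2.18 under Naprox in coculture.

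A further question was how far each drug moved the genes that fibroblasts had changed, with these genes picked in numbers the test did not use. Most drugs moved fibroblast-raised genes back down in coculture. In monoculture the medians of these genes hardly moved except under Diclo, with a median of 0.64 there (0.160 with an estimated correlation). The genes were picked for a lower level in MT than in MTF, so without fibroblasts there was no such rise to undo. The A77 median of 0.03 in monoculture joined 0.28 in number 1 and -0.27 in number 2. Under A77 in coculture 93.1% of 306 raised genes went down, with a median of -1.14 (adjusted p = 4.62e-40, and 0.00114 with an estimated correlation). Under Naprox 92.8% of 278 genes went down, with a median of -1.06 (adjusted p 0.00533 with an estimated correlation). Under AG it was 91.8% of 342 genes (0.000123 with an estimated correlation), and in library 3, which is not in doubt, 93.3%. Triple moved 88.2% of them down (0.00533 with an estimated correlation) and Dex 84.3% (0.00536), with library 1 of Triple at 88.6% and of Dex at 83.3%. The single Tofa library moved 87.3% of them down. Diclo moved 79.4% (0.021 with an estimated correlation, and 0.103 for genes picked at a log2 fold change of 0.58), Sulf 84.0% (0.0925), Hydrox 66.7% (0.267) and Meth 57.8%. Under Aur the median was 0.06, with 43.5% of genes down. Fibroblast-lowered genes went up under Naprox, with a median of 1.18 (91.1% of 135 genes; 0.0145 with an estimated correlation), and under AG (81.9% of 315 genes; 0.03), with AG library 3 at 93%. For A77 the lowered genes passed with an estimated correlation only with the number as a block (0.0326, against 0.0575), and for the other tested drugs in coculture they did not. Under Aur they had a median of -0.64, with 15.4% up.

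**Figure D5:**
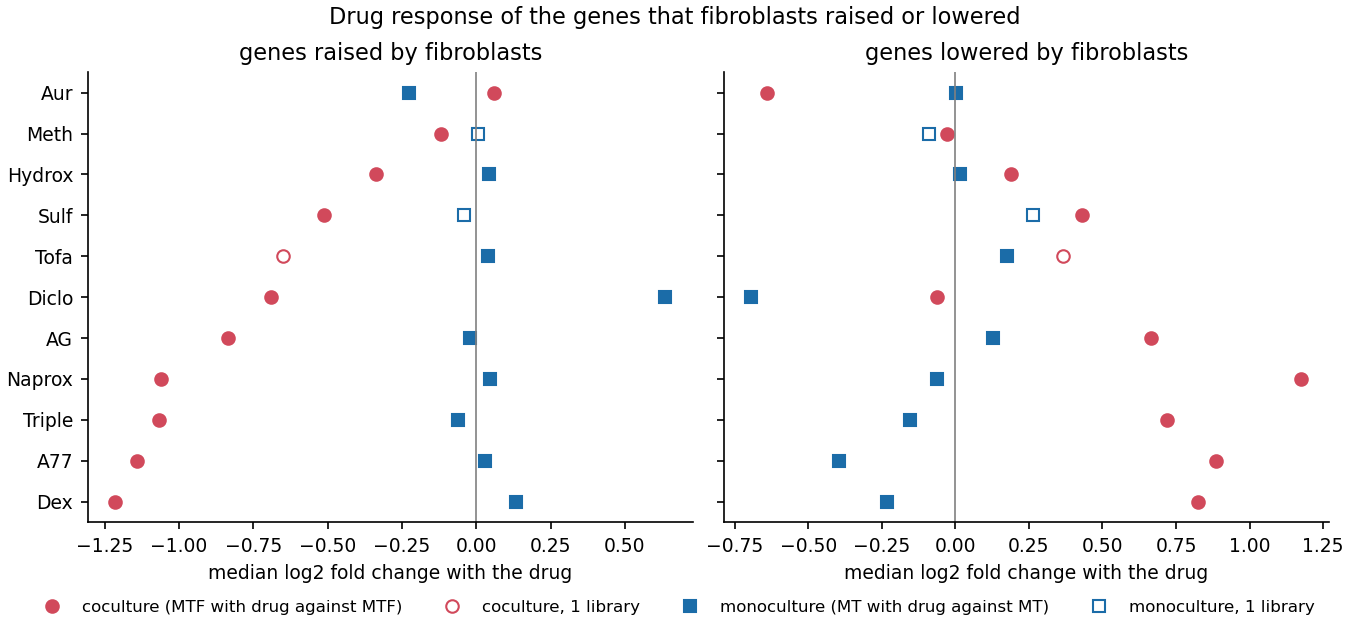
Median log2 fold change of genes that fibroblasts raised or lowered, by drug, in coculture (circles) and monoculture (squares), with open symbols for 1 library. The raised genes lie at -1.14 under A77 and -1.06 under Naprox in coculture, and at 0.06 under Aur.

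To ask whether a drug acts differently in coculture and monoculture, the difference of both effects was tested. For A77 the change of CREM lay lower in coculture than in monoculture, by 1.88 ± 0.27 on the log2 scale (adjusted p = 0.000503). That gap exceeds the fall of CREM under A77 in coculture, so the monoculture estimate showed no fall. Fibroblasts had raised CREM, so without them there was no such rise to undo. SIPA1L1, a regulator of the small G protein Rap (chromosome 14, 71787166 to 72207946), differed by -3.15 ± 0.54 for A77 (adjusted p = 0.00891), and these 2 genes were all that passed, against 4 with the number as a block and 3 without the libraries in doubt. Both calls ended without number 1, and leaving out number 2 or 3 ended 1 of them. For Naprox 4 genes passed, also without the libraries in doubt, and 59 with the number as a block. They were PRDM1, a repressor of differentiation genes (chromosome 6, 106441338 to 106557814), at -1.68 ± 0.17 (adjusted p = 0.00139), HEY1 (-4.30), SIPA1L1 (-3.46) and SLC36A4 (-1.61). SLC36A4 lies outside the naming rule and was chosen after its values were seen. Leaving out either number gave 0 genes. For Triple 17 genes passed, including CXCR7 (-9.35) and CREM (-1.3), and 4 of them with the number as a block, where CREM did not pass (adjusted p = 0.054), but 0 with edgeR without the libraries in doubt, with 443 at an unadjusted p under 0.05. CXCR7 (-7.73) and CREM (-1.06) were somewhat smaller there. The 17 also held TIE1 (-9.35), an endothelial transcript of MT_Triple library 2. For Aur, AG, Dex, Diclo and Hydrox edgeR called 0 genes, with 540, 506, 438, 204 and 141 at an unadjusted p under 0.05. The fit with the number as a block called 3 genes for Aur and 0 for AG, Dex, Diclo and Hydrox.

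The 2-day set held macrophages alone, with fibroblasts (MF), with TNF, and with both, in 1 library each, so differences are between libraries and no test was run. Fibroblasts with TNF again went with higher HBEGF and EREG. In MTF against MT, HBEGF stood at 290.6 against 1.174 CPM, a log2 ratio of 7.07. KCNE1L (7.68), EMR3 (7.43), CXCR7 (7.04) and CD93 had the other highest ratios, and HSD11B1 (-6.45), CCL19 (-6.04), MARCO and FFAR2 were among the lowest. EREG had a ratio of 4.94, PTGS2 of 4.26 and CXCL10 of -2.34. The cAMP list had a median of 2.19, with 14 of 16 genes at least 2-fold higher, above all 10000 random lists. Interferon-stimulated genes had a median of -1.39, with 20 of 27 at least 2-fold lower. Cholesterol synthesis genes had a median of -1.24 in MTF against MT and of 1.17 in MF against M. Fibroblasts without TNF (MF against M) left 332 of 8736 genes at least 2-fold apart, against 829 of 8679 for MTF against MT. LYVE1 (5.22), ENPP2, PLTP, FCGR1A and JAK3 were highest in MF, and PDK4 (-4.21), ATP6V0D2, MRC2, APOE and APOC1 lowest. In MT against M, 2270 of 9155 genes lay at least 2-fold apart, and TMM scaling moved the median over all genes from -0.114 to 0.027. CLU (10.53), MT1G, MT1H, AQP9 and CXCL5 had the highest ratios, and FOLR2 (-8.57), PDK4, IGF1, SLC40A1 and DHRS9 the lowest. In MTF against MF, 1983 of 8965 genes lay at least 2-fold apart, from IDO1 (9.38), CLU, GJB2, CXCL5 and MET down to LYVE1 (-8.93), IGF1, FOLR2, SEPP1 and KCNJ5.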

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

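The tests on the endothelial transcripts of MT_Triple library 2, on the MTF controls of A77 and Naprox and on the drug given to the mixed libraries were chosen after their results were seen, as were all values without the libraries in doubt.

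In 9 of 150 groups of 4 libraries, a library lay far from the others by Dixon's measure, where chance gives about 1 in 20 groups, or 7.5 here. The groups covered the total count and 49 genes in M, MT and MTF. Library 2 stood apart in 6 of them. ANKRD1 was highest in MTF library 2, at a log2 CPM of 0.66. CSGALNACT1 (2.01) and SHROOM3 (1.23) were highest and MS4A6A (8.71) was lowest in M library 2, which also held transcripts of MTF_Triple library 2. LAD1 was lowest in MT library 2, at 7.96. CXCL9 was highest in MT library 4, at 6.06, EREG lowest in M library 1, at 0.25, and SLC16A10 highest in MT library 3, at 2.24. MTF library 2 had the highest total count, at 45.74 megacounts against 26.25 for the next.

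A difference between cultures was called for A77, Naprox and Triple by testing the difference itself. The Triple calls ended without MT_Triple library 2 in the fit without a block, so in that fit they rest on this library. For A77 the difference covered 2 genes, SIPA1L1 at -3.15 and CREM at -1.88. For Naprox it covered 4 genes, among them HEY1 at -4.30, SIPA1L1 at -3.46 and PRDM1 at -1.68. Leaving out number 1 ended both A77 calls, and leaving out number 1 or 3 left 0 of the Naprox genes. For Triple 17 genes differed, with CXCR7 at -9.35 and CREM at -1.3, and 4 of them also with the number as a block, without CREM. The 17 also held TIE1 (-9.35), an endothelial transcript of MT_Triple library 2. The largest differences among them were PCDH1 (-16.50), PXDN (-15.51) and SEMA3F (-15.45). How many of the 17 are extra transcripts of that library was not tested gene by gene. Without that library edgeR called 0 of the 17. Without all 8 libraries in doubt CXCR7 still stood at -7.73 and CREM at -1.06. For Aur 0 genes passed, but 3 did with the number as a block. Gene lists also differed between cultures, 6 for A77, 6 for AG, 11 for Aur, 5 for Dex, 4 for Diclo, 5 for Hydrox, 3 for Naprox and 6 for Triple. With an estimated correlation 1 of the Diclo lists still did, the EGF family and receptors (0.0385, and 0.178 without the libraries in doubt), and 0 of the others.

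The first pattern weighed was the endothelial signal in MT_Triple library 2. The effect of Triple on macrophages is argued against, because the endothelial list changed by a median of 0 (quartiles -0.27 to 0.07) under Triple in numbers 1 and 3. RNA from the synovial fibroblasts is argued against as its source, although the fibroblast list lay higher by a median of 3.33 (quartiles -0.36 to 4.25), because the matrix genes COL1A1, COL1A2, COL3A1, DCN and LUM had a median of 2.4 CPM (highest 14), or 5.99% of the median of 40 CPM of the endothelial genes above every other library. RNA from endothelial cells stays open, since the median log2 ratio to the highest other library was 4.64, but only 15 of 20 genes lay above every other library, under a condition of 90% added after that median was seen, and VWF stood at 7.75 CPM against 8.78 elsewhere. Of the 20 endothelial genes 2 have a mean of at least 5 CPM in MT, and no biological explanation other than the drug was tested.

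The second pattern was the constant share of another library's transcripts in 7 libraries. An effect of the receiving library's own drug is argued against for MTF_Triple, MTF_AG and MT_AG library 2 and MT_Tofa library 1, because the share in another library of the same drug was at most 3.5% of that in the receiving library. For MTF_Dex and MT_Dex library 2 it was 173% and 136%, so there the drug's own effect cannot be told apart from mixing, because the genes tested stood higher in these libraries than in the AG libraries, and M library 2 had no drug. Mixing of RNA or reads between libraries of the same number may be the source, since genes of 5 to 20 CPM, which the scan had not used, also kept a nearly constant share, with a quartile ratio of at most 1.32. If both libraries of a pair were mixed, M library 2 would hold an estimated 49.6% from MTF_Triple library 2, which would hold 21.3% from M library 2. MTF_Dex library 2 would hold 45% from MTF_AG library 2, which would hold 30.5% in return. For MT_Dex and MT_AG library 2 the estimates were 41.4% and 29.6%. If mixing went only from MTF_Dex library 1, MT_Tofa library 1 would hold 19.2% from it. Whether mixing took place in the cultures, the RNA or the sequencing was not tested.

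The third pattern was that A77 and Naprox lowered fibroblast-raised genes in coculture. MTF control libraries out of place would shift every drug set against them. Aur and Meth, compared with the same MTF libraries, showed at most 10.3% of the shift. Both were picked after their shifts were seen, so the choice fixed the low value and no verdict on such a fault is drawn. A fault would have to be hidden under Aur and Meth by effects of their own, which was not tested. Against MTF libraries 1 and 2 the raised genes also went down under Dex (median -1.21), Triple (-1.07), Diclo (-0.69), Sulf (-0.51) and Hydrox (-0.34). Loss of the cAMP-responsive part of the fibroblast response may contribute, but the test made here cannot decide this. Under Naprox the 8 cAMP genes among those raised by fibroblasts had a median of -2.24 and the other 270 a median of -1.02 (one-sided permutation p = 0.0108, 100000 resamples). Genes are not independent replicates, and the resampling did not match them on how far fibroblasts had raised them. A fall in proportion to that rise stays open, as does a shared cause other than cAMP. A77 was not tested in this way.

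Other splits of the libraries were tried for each comparison of at least 3 libraries per group, in fits of those libraries alone. For TNF 4523 genes passed, and at most 1 in any other of 35 splits. For fibroblasts 1122 passed and at most 6 in another split, and for TNF with fibroblasts 4486 and at most 1. In each of these 3 the real split alone gave as many genes over the 35 splits. These splits ignore the numbers, and libraries of the same number correlate, so no verdict on chance is drawn from them. Of these splits 8 part all 4 pairs of the same number, too few for a share under 0.05, and the other 7 gave 0 genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 647 and 0 genes for Aur in monoculture, 59 and 1 for Triple in coculture, 28 and 0 for A77 in coculture, 2 and 1 for Aur in coculture, and 2 and 0 for Triple in monoculture. For Naprox and A77 in monoculture all 10 splits gave 0. For the culture differences there are 4 splits, also too few, with 3 and 0 genes for A77, 2 and 0 for Aur, and 0 in all 4 for Triple.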

How the results depend on the processing

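The fits without MT_Triple library 2, without the 8 libraries in doubt, of the compared groups with a block, and of the compared groups alone for drugs were chosen after the data were seen. Depth limited genes near the floor, and the few libraries per drug limited small changes. In simulation Dex in coculture recovered 1.5% of 1.5-fold changes and 48.5% of 4-fold changes. The simulated counts had no difference between numbers and took their spread from a fit without the block. They therefore do not show what the block recovers in the real data. Without the 8 libraries in doubt, AG and Dex in each culture and Tofa in monoculture have 1 library, assumed to vary like the other groups.

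None of the genes chosen by the naming rule reversed. Among other genes given above, IL6 under TNF and SEPP1 and FOLR2 under Triple in coculture changed sign without the 8 libraries in doubt. Of 144 results on genes chosen by that rule, DESeq2 ended the call of 0 and added 4. Of 151, other size factors ended 4, no filter 15 and the block 1, and the block added 4. Without the 8 libraries in doubt 30 of 151 calls ended, and without MT_Triple library 2 14 of 138. Leaving out numbers 1 to 4 ended 56 of 141, 48 of 138, 76 of 129 and 4 of 60. Gene counts by edgeR for TNF, alone and with fibroblasts, stayed within 1.5 times under every setting but leaving out number 3.

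With the number as a block the counts were 3250 for fibroblasts, and in coculture 1069 for A77, 206 for AG, 388 for Aur, 430 for Dex, 39 for Hydrox, 754 for Naprox and 2716 for Triple. In monoculture they were 1 for A77, 1540 for Aur, 199 for Dex, 11 for Diclo, 53 for Hydrox and 2697 for Triple, and for culture differences 4 for A77, 3 for Aur, 59 for Naprox and 4 for Triple. With the block and without MT_Triple library 2 they were 3397 for fibroblasts, 1156 for A77, 259 for AG, 429 for Aur, 441 for Dex, 2 for Diclo, 43 for Hydrox and 2867 for Triple in coculture. In monoculture they were 2 for A77, 1634 for Aur, 222 for Dex, 11 for Diclo, 68 for Hydrox and 953 for Triple, and for culture differences 5 for A77, 3 for Aur, 1 for Dex, 1 for Diclo and 2 for Triple. With the block and without the 8 libraries in doubt they were 3623 for fibroblasts, 1272 for A77, 148 for AG, 486 for Aur, 347 for Dex, 3 for Diclo, 64 for Hydrox, 754 for Naprox and 2150 for Triple in coculture. In monoculture they were 8 for AG, 1754 for Aur, 289 for Dex, 0 for Diclo, 28 for Hydrox and 1063 for Triple, and for culture differences 12 for A77, 11 for Aur, 54 for Naprox and 2 for Triple. The cause of these rises was not tested.

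DESeq2 called 491 genes for A77, 425 for AG, 253 for Aur, 475 for Dex, 52 for Diclo, 101 for Hydrox, 6 for Meth, 735 for Naprox, 5 for Sulf and 1619 for Triple in coculture. In monoculture it called 14 for A77, 22 for AG, 1086 for Aur, 292 for Dex, 82 for Diclo, 205 for Hydrox, 9 for Naprox and 17 for Tofa, and the cause was not tested.

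A fit of the compared groups alone, which has fewer libraries to estimate spread, gave 1122 genes for fibroblasts, 59 for Triple, 28 for A77 and 2 for Aur in coculture, 2 for Triple in monoculture, and 2 for Aur and 0 for Triple as culture differences. With a block as well it gave 5005 for fibroblasts, 370 for A77 and 595 for Aur in coculture, and 1210 for Aur, 106 for Naprox and 0 for Triple in monoculture. No filter, which tests more genes, gave 2 for AG in coculture and, as culture differences, 11 for Naprox and 10 for Triple. Without MT_Triple library 2 edgeR called 239 for Triple in monoculture and 0 as a culture difference. Without the 8 libraries in doubt it called 0 for AG, 11 for Hydrox and 617 for Triple in coculture, 132 for Dex, 0 for Diclo, 1 for Hydrox and 245 for Triple in monoculture, and 0 for Triple as a culture difference. The cause of these was not tested apart from the fewer libraries.

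Leaving out each number in turn gave 2925 to 5784 genes for TNF, 227 to 1946 for fibroblasts and 3208 to 6118 for TNF with fibroblasts. In coculture it gave 2 to 236 for A77, 0 to 27 for AG, 0 to 99 for Aur, 2 to 12 for Dex, 36 to 1180 for Triple, and 0 for Diclo, Hydrox and Naprox. In monoculture it gave 0 to 1 for A77, 0 to 6 for AG, 19 to 1000 for Aur, 0 to 5 for Dex, 0 for Diclo, 0 to 13 for Hydrox, 0 to 4 for Tofa and 0 to 1461 for Triple. As culture differences it gave 0 to 2 for A77, 0 to 6 for Aur, 0 for Naprox and 0 to 1 for Triple. Fewer libraries entered each of these fits.

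Of 188 list tests past 0.05, 15 passed with an estimated correlation, which allows for genes that move together. With the number as a block 166 kept their call and 22 lost it. Without the 8 libraries in doubt 152 kept their call, 32 lost it and 4 reversed. The glucocorticoid list then stood at -0.152 under AG in coculture, from 0.76, at -0.398 under AG in monoculture and at -0.17 under Tofa in monoculture, where the removed libraries held Dex transcripts. The proliferation list stood at 0.038 for Triple in coculture against monoculture, and the cause was not tested. For genes that fibroblasts had changed, an estimated correlation ended the calls of these medians. Lowered genes lost theirs at 0.885 for A77, -0.641 for Aur, 0.823 for Dex, 0.188 for Hydrox, -0.027 for Meth, 0.431 for Sulf and 0.719 for Triple in coculture. In monoculture they did at -0.394 for A77, -0.231 for Dex, -0.694 for Diclo and -0.154 for Triple. Raised genes lost theirs at 0.061 for Aur, -0.336 for Hydrox and -0.511 for Sulf in coculture, and at 0.134 for Dex and 0.636 for Diclo in monoculture. With the block the lowered genes gained a call at 0.129 for AG and 0.174 for Tofa in monoculture, neither of which passed with an estimated correlation as well (0.978 for both), and lost it at -0.027 for Meth in coculture. Picking genes at a log2 fold change of 0.58 gave them calls at 0.09 for AG, -0.171 for Naprox and 0.103 for Tofa in monoculture, none of which passed with an estimated correlation (0.897 for each). It ended those at -0.103 for Triple in monoculture and at 0.031 for Meth in coculture, which reversed. Under Diclo in coculture the raised genes, at -0.344, then did not pass with an estimated correlation, and the cause was not tested.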

Other observations

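The comparison of Triple with Hydrox and the test without sterol and lysosome genes were set out before their results were seen.

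Triple and Hydrox changed genes in a similar way, and the labels do not spell out what Triple holds. Across 9738 genes the Triple effect in monoculture (numbers 1 and 3) correlated with the Hydrox effect in coculture (numbers 1 and 2) at r = 0.642, while for the other drugs r lay between -0.073 and 0.179. Genes are not independent replicates, and with no shared number r was 0.497. Triple may hold the same compound as Hydrox, or a compound with like effects, which this test does not part. The members of the cholesterol synthesis and lysosome lists alone do not make the correlation, since 99.2% of it was left without them. They are few among these genes, and sterol-regulated genes outside the lists, such as EBP and TMEM97, were kept, so a wider sterol response stays open.

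In the 2-day set the cholesterol synthesis list went in opposite directions under TNF with and without fibroblasts. Its median log2 ratio was 1.25 for TNF alone (MT against M) and -1.10 for TNF with fibroblasts present (MTF against MF). With 1 library per group this difference was not tested.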
